A study of Mus musculus with 76 samples.

How the data were processed

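Polyadenylated RNA was sequenced from single mouse oocytes, 2-cell embryos, blastocysts and pieces of extraembryonic ectoderm (ExE) at embryonic day 6.5. Each of the 76 libraries, at 4 stages, is wild type (WT) or Ezhip maternal knockout (matKO), per the labels, which also give the sex of every library. Per the labels' protocols, libraries were built with a kit for unique dual indexing of DNA. The deposited tables hold whole-number counts per gene, 1 table per stage, together with the chromosome, start, end, strand and length of each gene. Trim Galore, STAR, SAMtools and featureCounts, and the mouse build mm10, are named by the submitters' processing notes without versions. Strand settings, the treatment of reads that match several places, and the annotation release are not given in the sources used here. Genes with near-identical copies are therefore reported as uncertain. Counts on the mitochondrial chromosome were 0 in every library, so no mitochondrial share was used. The tables also hold 8 columns of counts with no matching sample in the labels; these were not used.

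Libraries were grouped by stage, genotype and sex from the labels. Litter, culture and oocyte donor are not given, so p-values measure the spread between single libraries, which may be partly technical. No pair of libraries in a group agreed within sampling noise: the lowest chi-square per degree of freedom was 10.2, over genes with at least 20 counts in a pair. The library identifiers carry prefixes. Blastocysts of both genotypes came under the prefixes D405T and D707T, and the prefix was a term of the blastocyst model. Within D707T the identifier numbers ran from 1 to 4 in WT and from 5 to 12 in matKO blastocysts. Order and genotype thus cannot be told apart there, whereas within D405T the numbers of the genotypes were interleaved. In oocytes the numbers also separated the genotypes, with 17 to 19 in WT and 21 to 24 in matKO. All WT ExE libraries had the prefix D1042C and all matKO ExE libraries had D707T, so prefix and genotype cannot be told apart in ExE.

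Each stage was fitted on its own. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10. This left 14838 genes in oocytes, 14506 in 2-cell embryos, 13445 in blastocysts and 14156 in ExE, of 48321 in the tables. Library sizes were scaled by TMM. The test chosen before the data were examined was edgeR's quasi-likelihood test (glmQLFit with robust and legacy=FALSE, then glmQLFTest), with sex as a term. Female, male and genotype-by-sex effects came from a model with a mean for each genotype and sex. P-values were adjusted by Benjamini-Hochberg over the genes of a stage, with a threshold of 0.05. Standard errors (SE) are those implied by the F statistic. Fold changes are log2, matKO over WT, unless a fold is named. Levels are TMM-scaled counts relative to the library total (CPM) with the standard deviation (SD) between libraries, and log2 CPM uses a prior count of 2. Where a number of matKO libraries follows a change, these lay on that side of the WT mean, unless every WT library is named.

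The procedure was tested on simulated counts with the means, spreads and library sizes of each stage and 200 genes changed by 2-fold or 4-fold, in 3 draws. Of the genes called in these simulations, 13.1% in oocytes, 29.2% in 2-cell embryos, 20.4% in blastocysts and 15.1% in ExE were unchanged genes, more than the threshold allows. With edgeR's older fit, which estimates dispersions by estimateDisp first, the shares were 5.23%, 4.67%, 2.99% and 3.44%. The simulated counts were negative binomial with the spreads that estimateDisp gave, so the simulation may favour the older fit. The shares in the real data may differ for both fits. The planned test recovered 47% of the 4-fold changes in oocytes, 70% in 2-cell embryos, 78.7% in blastocysts and 74.3% in ExE, and 8.33%, 19.7%, 48.7% and 21% of the 2-fold changes. The planned test was kept as the main one. The second adjusted p given in parentheses or after "with estimateDisp" is from the older fit, and counts from that fit follow the main counts of lists with a called member. The older fit was planned for the 4 genotype effects and was added for the sexes and single genes after the simulations were seen.

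Named genes followed a rule: Ezhip; the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and a standard symbol; every tested member of the core noncanonical imprinted list; up to 4 called members with the smallest p from each other list; and up to 5 called genes with the smallest p in each sex and for the interaction. Some genes that this rule selects are not reported here. Gene lists were tested as sets with camera and fry of limma 3.58.1 on voom values, for lists with at least 3 tested genes, and camera was repeated with an estimated correlation between genes. Genes on chromosome X without Xist and Ezhip, and genes within 5 Mb of Ezhip, were further lists. For the genotype effects over both sexes, no list that passed with the preset correlation passed with the estimated one. X-linked output was the mean log2 CPM of X-linked genes minus that of autosomal genes in each library. It was compared between genotypes within sex by two-sided exact permutation tests, and between sexes by a two-sided permutation test with 100000 draws. Overlaps between stages were tested with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over the 6 overlaps.

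The alternatives tried were DESeq2 1.42.0 and its size factors, limma-voom, no count filter, a fold of at least 2, removal of each library in turn, a block for the replicate number, and models without the sex or prefix term or within a prefix. Alternatives added after seeing the data were a correction for GC content (lowess span 0.3), the identifier number as a covariate in 2-cell embryos, expression-matched autosomal genes (5 for each X-linked gene), and fits without libraries high in markers of other cell types. Counts of list members within each blastocyst prefix, and a test of the genotype effect between prefixes, were also added then. Other splits of the libraries were drawn up to 100 times within sex and, for blastocysts, prefix, and 50 times for the older fit. Principal components used the 2000 genes of highest variance. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. A fold against a group with 0 counts was set against a floor of 3 counts over that group. Ratios with few counts carry a 95% exact Poisson interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.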

Results

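The series followed gene expression in mice whose mothers lacked Ezhip, the gene of an inhibitor of the Polycomb complex PRC2, which places the H3K27me3 histone mark. It asked how the loss of the maternal product affects early development and the imprints that depend on this mark. Single oocytes were profiled from WT (n = 3) and matKO (n = 4) females. The 2-cell embryos numbered 11 WT (5 female, 6 male) and 12 matKO (6 female, 6 male). There were 14 WT blastocysts (6 female, 8 male) and 14 matKO blastocysts (7 female, 7 male). ExE, the trophoblast tissue next to the embryo proper, came from 10 WT (6 female, 4 male) and 8 matKO (5 female, 3 male) conceptuses. Total counts per library, in megacounts (M), ran from 5.27 to 26.5 M in oocytes, from 1.05 to 14.1 M in 2-cell embryos, from 4.06 to 32 M in blastocysts and from 2.74 to 26.7 M in ExE. Median totals for WT and matKO were 12.3 and 12 M in oocytes, 5.82 and 4.22 M in 2-cell embryos, 18.8 and 11.7 M in blastocysts, and 9.08 and 13.2 M in ExE. Counts of 4 Y-linked genes summed to between 0 and 28 in the 42 libraries labelled female and to between 52 and 5697 in the 34 labelled male.

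Ezhip, listed in the files as AU022751, lies on chromosome X from 6081219 to 6083419 on the minus strand of mm10 and has 3 annotated intervals that span 2201 bases. Which part was deleted is not given in the sources used here. In oocytes it stood at 1280 CPM ± 306 (SD, n = 3) in WT and 0.283 CPM ± 0.199 (SD, n = 4) in matKO, a log2 fold change of -12.35 (adjusted p 2.7e-10, and 5.3e-07 with estimateDisp), lower in 4 of 4 matKO oocytes. WT 2-cell embryos held 216 CPM ± 87 (SD, n = 5) in females and 102 CPM ± 46.2 (SD, n = 6) in males. Their matKO counterparts held 5.22 CPM ± 6.87 (SD, n = 6) and 1.62 CPM ± 3.49 (SD, n = 6). The log2 fold change was -5.39 (adjusted p 9.9e-12, and 9.4e-06 with estimateDisp), and all 12 matKO embryos lay below every WT embryo. In blastocysts the gene was near the limit of detection except in some WT males, with 9.55 CPM ± 15.7 (SD, n = 8) in WT males, 1.04 CPM ± 1.46 (SD, n = 6) in WT females, 0.105 CPM ± 0.179 (SD, n = 7) in matKO males and 0.637 CPM ± 0.689 (SD, n = 7) in matKO females. Ezhip fell there by 3.92 on the log2 scale (adjusted p 9e-05, and 0.045 with estimateDisp), with 14 of 14 matKO blastocysts under the WT mean. Within D405T it was at -2.03 and not called (adjusted p 0.19, and 0.56). Within D707T it was at -5.06 (adjusted p 0.0024, and 0.045). Over both prefixes the male change was -7.19 (adjusted p 5.6e-05) and the female change -1.39 (adjusted p 0.58). The test of the difference between the sexes gave an adjusted p of 0.87. Ezhip is X-linked, and a son's X comes from the mother. In males, loss of the maternal product and of the embryo's own copy thus cannot be told apart. In ExE the gene had too few counts to be tested, with means of 0.411 CPM in WT females, 0.314 CPM in WT males, 0.282 CPM in matKO females and 0.0383 CPM in matKO males. No library went against its genotype label where the gene was well expressed.

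**Figure D1:**
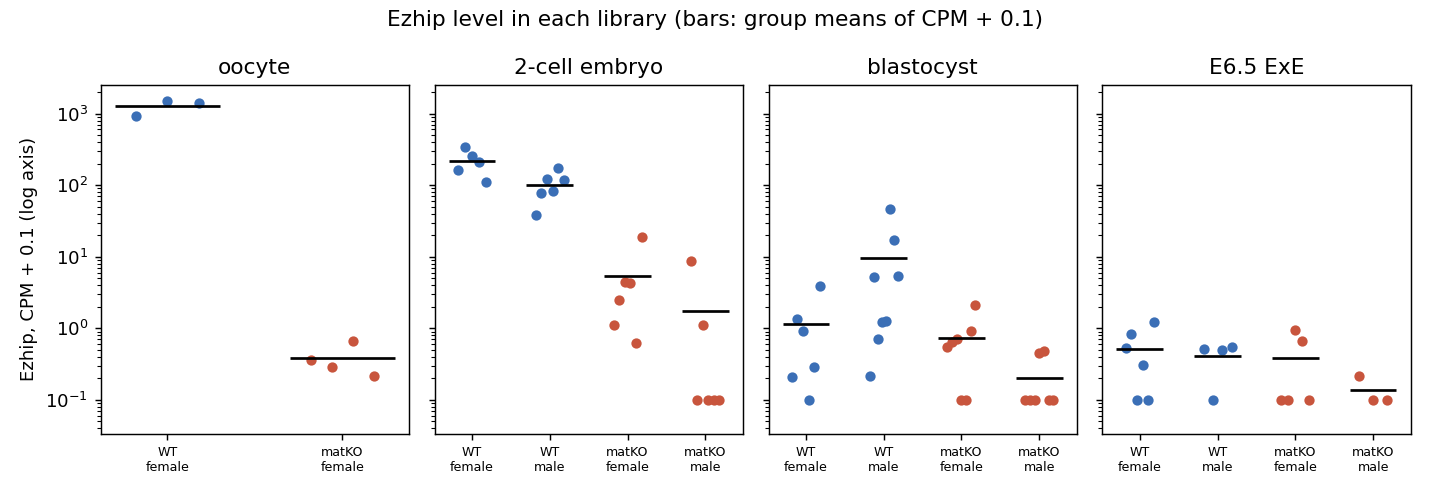
Ezhip level of each library by stage, genotype and sex, as CPM + 0.1 on a log axis; each point is a library and each bar is the mean of its group. All 4 matKO oocytes and all 12 matKO 2-cell embryos lie below every WT library of their stage.

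Oocytes show whether maternal RNA already differed before fertilization. Besides Ezhip, Aldh1a1, which makes retinoic acid, and Cyp11a1, the first enzyme of steroid synthesis, fell in matKO oocytes. Aldh1a1 went from 136 CPM ± 40.1 (SD, n = 3) to 26.5 CPM ± 2.72 (SD, n = 4), and Cyp11a1 from 262 CPM ± 64.8 (SD, n = 3) to 58.7 CPM ± 9.83 (SD, n = 4). Their log2 fold changes were -2.38 ± 0.25 (SE) and -2.18 ± 0.22 (SE), each with an adjusted p of 0.0059 (0.0068 with estimateDisp), and each was lower in 4 of 4 matKO oocytes. These 3 genes were the only ones called of 14838 tested, by either edgeR fit, and 1214 genes had an unadjusted p under 0.05. DESeq2 called 36. Without matKO oocyte 1 the count was 1, and Aldh1a1 and Cyp11a1 were no longer called (adjusted p 0.054 and 0.053); without WT oocyte 2, Aldh1a1 was not called (adjusted p 0.068).

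Markers of decidua and uterine stroma were lower as a set in matKO oocytes, with a median log2 fold change of -1.69 over 13 tested genes (camera adjusted p 1.5e-09). None passed over all genes, 7 were lower when adjusted over the list alone, and the set had an adjusted p of 0.54 with an estimated correlation. Genes of ribosome biogenesis were shifted up by a median of 0.27 over 22 genes (camera adjusted p 0.0019), with 0 called over all genes, 0 adjusted over the list alone, and an adjusted p of 0.64 with an estimated correlation. Markers of cumulus and granulosa cells, the somatic cells around the oocyte, included 1 called gene of 15, Cyp11a1, with 3 lower adjusted over the list alone; their mean level was 5.24 log2 CPM ± 0.43 (SD, n = 3) in WT and 5 log2 CPM ± 0.63 (SD, n = 4) in matKO. The noncanonical imprinted genes Gab1, Jade1, Smoc1 and Xist were not called, with log2 fold changes of -0.26, 0.36, -2.23 and 1.64; 0 of these 4 were called over all genes and 1 was lower adjusted over the list alone (camera adjusted p 0.62). Developmental transcription factors targeted by PRC2 had 0 of 30 called, with 2 higher adjusted over the list alone and a median of 0.58 (camera adjusted p 0.074). Subunits of PRC2 itself had 0 of 14 called, by either count.

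In 2-cell embryos, where the embryonic genome is first transcribed, some transcripts typical of this stage were higher in matKO embryos. Zfp352 rose from 65.8 CPM ± 50.2 (SD, n = 11) to 342 CPM ± 253 (SD, n = 12), a log2 fold change of 2.37 ± 0.49 (SE), and was above the WT mean in 12 of 12 matKO embryos (adjusted p 0.0088, and 0.039 with estimateDisp). Tcstv3, of a multicopy family and therefore uncertain, was at 2.05 (adjusted p 0.02, and 0.047), in 11 of 12 embryos. The deubiquitinase genes Usp17lb and Usp17lc, likewise of a multicopy family whose reads may be shared, had values of 1.88 (adjusted p 7.7e-04, and 0.0016) and 2.84 (adjusted p 0.012, and 0.032), in 12 and 8 of 12 embryos. Of 22 tested transcripts of this list, 7 rose and 0 fell, 4 rose with estimateDisp, and 11 were higher adjusted over the list alone. The median log2 fold change was 0.88 (camera adjusted p 2.7e-09; adjusted p = 0.28 with an estimated correlation). The mean level of the list was 5.02 log2 CPM ± 0.67 (SD, n = 11) in WT and 6.08 log2 CPM ± 0.82 (SD, n = 12) in matKO, and 7 of 12 matKO embryos lay above every WT embryo. These 7, with identifier numbers from 42 to 48, also stood apart on the first principal component, at 39.7 to 72.1, where WT embryos reached 9.6.

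Maternal transcripts stored in the oocyte were also shifted up, by a median of 0.54 over 33 genes (camera adjusted p 1.9e-05; adjusted p = 0.66 with an estimated correlation). Gdf9, an oocyte growth factor, rose by 0.75 (adjusted p 0.019, and 0.037 with estimateDisp) in 12 of 12 embryos, and Omt2b by 0.83 (adjusted p 0.044, and 0.095) in 10 of 12. These 2 were the only called members, 1 with estimateDisp, and 13 were higher and 1 lower adjusted over the list alone. Immediate early and stress genes had a median of 0.59 over 17 genes (camera adjusted p 0.0021; adjusted p = 0.7 with an estimated correlation), with 0 called over all genes and 9 higher and 1 lower adjusted over the list alone. Outside the lists, the largest rises among well-expressed genes included Tacr3, a neurokinin receptor, by 5.99 ± 0.63 (SE), above every WT embryo in 12 of 12 matKO embryos (adjusted p 6.2e-07, and 1.7e-05). Slc26a1, an anion transporter, rose by 3.24 (adjusted p 7.7e-04, and 0.027) in 11 of 12. Alox15 rose by 7.09 (adjusted p 0.0058, and 0.014), but its matKO level of 29.5 CPM had an SD of 94.4 and it was above the WT mean in 8 of 12. Saa3 and C1qb were called at 4.64 and 3.26 (adjusted p 0.015 and 0.021) in 6 and 9 of 12 embryos, and not with estimateDisp (adjusted p 0.24 and 0.15).

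Some genes of steroid-producing granulosa cells fell in matKO 2-cell embryos. Cyp11a1 had 5119 counts over the WT libraries and 0 over the matKO libraries, at least 1750-fold lower (adjusted p 0.0081, and 0.0026 with estimateDisp), with 12 of 12 under the WT mean of 105 CPM ± 109 (SD, n = 11). Hsd3b1 fell by 10.73 on the log2 scale (adjusted p 0.0092, and 1.7e-05) and the inhibin subunit gene Inha by 7.94 (adjusted p 0.0087, and 5.2e-04), each in 12 of 12 embryos. Star, which carries cholesterol into mitochondria, fell by 2.99 (adjusted p 0.021) in 12 of 12 and was not called with estimateDisp (adjusted p 0.19). For Cyp11a1, Hsd3b1, Inha and Star, 0 of the 12 matKO embryos lay below every WT embryo. Of 14 tested markers of cumulus and granulosa cells, 4 fell and 0 rose, 3 fell with estimateDisp, and 5 were lower adjusted over the list alone; the set itself did not pass (median -0.75, camera adjusted p 0.36). Their mean level was 3.12 log2 CPM ± 1.62 (SD, n = 11) in WT and 1.51 log2 CPM ± 0.26 (SD, n = 12) in matKO, with 8 of 11 WT embryos above every matKO embryo. Markers of decidua and uterine stroma stood at 1.62 log2 CPM ± 1.57 (SD, n = 11) in WT and 0.65 log2 CPM ± 0.72 (SD, n = 12) in matKO, and the same 8 WT embryos lay above every matKO embryo. Of 9 tested, edgeR called 0 with either fit, and 2 were lower adjusted over the list alone (median -1.49, camera adjusted p 0.36). Aldh1a1 fell by 6.14 (adjusted p 7.7e-04, and 0.0034) and the trophoblast regulator Hand1 by 5.70 (adjusted p 7.7e-04, and 1.2e-04), both in 12 of 12. Below every WT embryo lay 0 of 12 for Aldh1a1 and 10 of 12 for Hand1. The globin gene Hbb-bs, which has a near-identical copy and is uncertain, had 797 counts in WT and 0 in matKO, at least 167-fold lower (adjusted p 0.044, and 0.032).

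Among noncanonical imprinted genes, whose maternal copies are silenced through H3K27me3, Gab1 fell at the 2-cell stage by 2.04 ± 0.46 (SE) (adjusted p 0.013), in 12 of 12 embryos, but was not called with estimateDisp (adjusted p 0.1). It was the only called gene of the 7 tested (0 with estimateDisp), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p 0.36). Sfmbt2, Slc38a4, Jade1, Smoc1, Xist and Platr20 had log2 fold changes of 0.20, 0.13, -0.22, -1.61, -3.29 and 1.22. In all, edgeR called 454 of 14506 genes, 199 higher and 255 lower, and the fit with estimateDisp called 106, 45 higher and 61 lower, of which 102 were shared; voom called 49 and DESeq2 693. Counts moved by over 1.5 times without WT female 1 (256), matKO females 1 (686), 4 (736) and 6 (288), and matKO males 1 (260), 2 (296), 3 (245), 5 (284) and 6 (261).

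By sex, 10 genes were called in female 2-cell embryos and 807 in males, against 3 and 127 with estimateDisp. In females Akr1cl, of the aldo-keto reductase family, fell by 3.76 (adjusted p 0.0096, and 0.0089 with estimateDisp). Tmem126a and Trp53bp2 fell by 3.28 and 2.97 in females (adjusted p 0.016 and 0.031; 0.57 and 0.31 with estimateDisp). In males Pramef25, of a multicopy family and uncertain, was at 3.46 (adjusted p 2.1e-04, and 0.0017). Tacr3 rose by 7.03 (adjusted p 2.1e-04, and 0.0017), Usp17lb by 2.59 (adjusted p 5.9e-04, and 0.0017) and 1700019M22Rik by 3.54 (adjusted p 8.8e-04, and 0.0051). The genotype-by-sex test of edgeR called 0 genes, with 1684 at an unadjusted p under 0.05 (930 with estimateDisp), and DESeq2 also called 0. It called 201 with no count filter and 129 with the identifier number as a covariate, none of which passed in the planned test. Sex went with library order in matKO embryos: 4 of 6 females but 1 of 6 males had identifier numbers from 37 to 41.

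Blastocysts test the maternal effect at the first lineage decision, when imprinted X inactivation rests on Xist from the paternal X. Xist, the RNA that silences an X chromosome, rose in matKO male blastocysts, to 85.3 CPM ± 96.4 (SD, n = 7) from 1.33 CPM ± 1.5 (SD, n = 8) in WT males. All 7 matKO males, at 13.6 to 286 CPM, lay above all 8 WT males, at 0 to 4.1 CPM. Y-linked genes stood at 122 CPM ± 60.6 (SD, n = 7) in matKO males and 147 CPM ± 42.7 (SD, n = 8) in WT males, and were lowest, at 36.2 CPM, in matKO male 4, which had the most Xist. The male log2 fold change was 5.60 ± 0.66 (SE; adjusted p 4.8e-06, and 7.2e-05 with estimateDisp). The female log2 fold change, fitted with the prefix as a term, was -0.18 (adjusted p 0.92). The female means, which are not adjusted for the prefix, were of the opposite order, 415 CPM ± 178 (SD, n = 6) in WT and 431 CPM ± 211 (SD, n = 7) in matKO. The female minus male difference of -5.78 ± 0.79 (SE; adjusted p 1.4e-04, and 0.003 with estimateDisp) made Xist the 1 gene of 13445 called for the interaction by either fit, where DESeq2 called 4; within the prefix D707T, with 1 WT female, 0 were called.

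X-linked genes were lower in matKO blastocysts of both sexes. Of 466 tested, 136 fell and 19 rose (92 and 15 with estimateDisp; 160 lower and 28 higher adjusted over the list alone), so 29.2% of X-linked genes fell against 7.01% of autosomal genes. Chromosome X had the lowest median log2 fold change of 20 chromosomes, -0.356, with autosomes between -0.074 and 0.025. The set had a camera adjusted p of 2.7e-07 and an adjusted p = 0.12 with an estimated correlation. In males the median was -0.57 (camera p 2.5e-12; p = 0.0013 with an estimated correlation), with 80 lower and 12 higher (37 and 7 with estimateDisp; 137 and 12 adjusted over the list alone). In females it was -0.18 (camera p 0.0012; p = 0.1 with an estimated correlation), with 39 lower and 8 higher (4 and 1 with estimateDisp; 80 and 16 adjusted over the list alone). The sexes differed by this test (camera p 2.1e-06; p = 0.019 with an estimated correlation).

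Per library, X-linked output relative to autosomes was -0.54 ± 0.21 (SD, n = 8) in WT males and -1.39 ± 0.51 (SD, n = 7) in matKO males, a difference of -0.85 log2 units (exact permutation p 4.66e-04). In females it was -0.38 ± 0.15 (SD, n = 6) in WT and -0.99 ± 0.44 (SD, n = 7) in matKO, a difference of -0.61 (exact permutation p 0.00816). Both comparisons were made without regard to the prefix, and D707T held 1 of the 6 WT females but 4 of the 7 matKO females. Prefix and genotype are thus partly mixed in them. Within the prefix D405T the differences were -0.50 in males and -0.24 in females, each with the smallest p that exact permutation allows (0.0179; 5 WT, 3 matKO). In D707T males the difference was -1.06 (exact permutation p 0.0571; smallest possible 0.0286; 3 WT, 4 matKO), and D707T held 1 WT female, too few to test. The female minus male difference of this measure over both prefixes was 0.24 (permutation p 0.543, without regard to the prefix). The same measure did not differ beyond the spread in oocytes (-0.11, exact permutation p 0.314), female 2-cell embryos (-0.09, exact permutation p 0.141) or male 2-cell embryos (-0.01, exact permutation p 0.89).

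**Figure D2:**
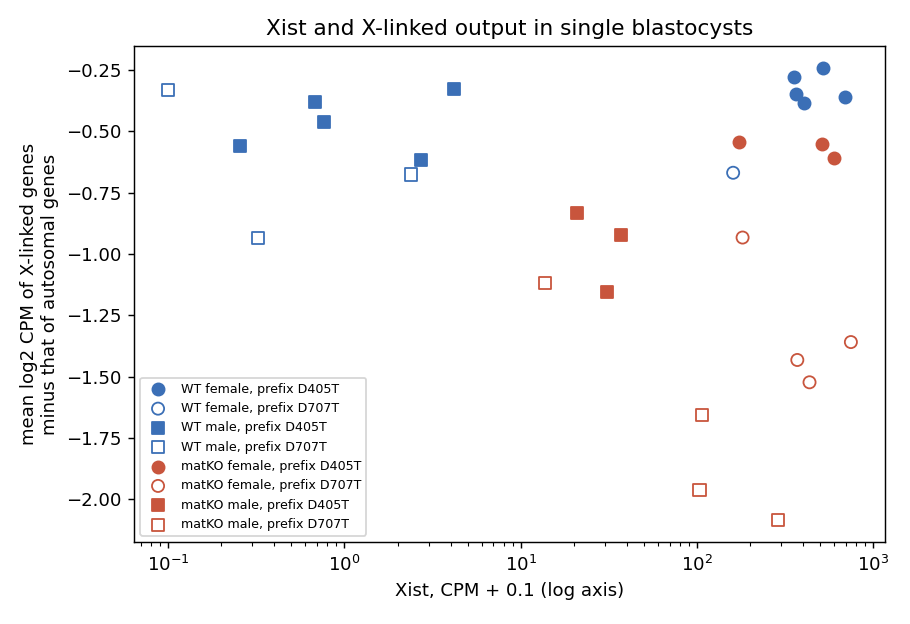
X-linked minus autosomal mean log2 CPM of each blastocyst against its Xist level (CPM + 0.1, log axis), by genotype, sex and identifier prefix; each point is a library. The 7 matKO males lie to the right of all 8 WT males and mostly below them.

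**Figure D3:**
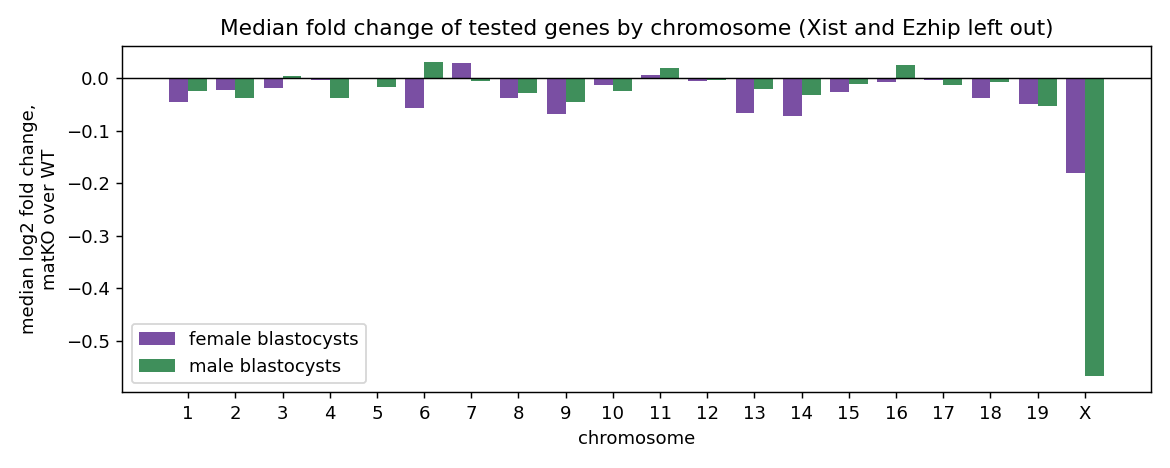
Median log2 fold change (matKO over WT) of tested genes on each chromosome in female and male blastocysts, without Xist and Ezhip. Bars show medians; chromosome X has the lowest in both sexes, -0.181 in females and -0.568 in males.

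Noncanonical imprinted genes moved in both directions in matKO blastocysts. Gab1, an adaptor of growth factor receptors, rose by 0.77 ± 0.16 (SE), to 183 CPM ± 61.2 (SD, n = 14) from 110 CPM ± 21.2 (SD, n = 14) (adjusted p 0.0014, and 0.0047 with estimateDisp), in 12 of 14 embryos. The noncoding RNA Platr4 rose by 1.16 (adjusted p 0.0018, and 0.019), in 13 of 14. Slc38a4, an amino acid transporter, fell by 0.73 (adjusted p 0.0045, and 0.014), in 14 of 14. Sfmbt2, Jade1, Smoc1 and Platr20 had values of -0.35, 0.35, 0.61 and 0.29 and were not called. Thus 2 of 8 tested rose and 1 fell (also with estimateDisp), 5 were higher and 1 lower adjusted over the list alone, and the set had a camera adjusted p of 0.099. In the wider list of candidates 2 of 14 rose and 3 fell (2 and 2 with estimateDisp; 3 and 3 adjusted over the list alone), led by Epas1, a hypoxia factor, at 1.19 (adjusted p 1.2e-04, and 5.7e-04; 14 of 14 embryos), with Slc38a1 and Otx2 lower. Of canonical imprinted genes, Snrpn rose by 0.58 (adjusted p 0.0029, and 0.0073) and Mcts2 by 0.75 (adjusted p 0.016, and 0.039), each in 14 of 14; 4 of 14 paternally expressed genes rose and 0 fell (2 and 0 with estimateDisp; 5 and 0 adjusted over the list alone; camera adjusted p 0.058). H19, Meg3 and Osbpl5 were the 3 of 10 maternally expressed genes that fell, none of them with estimateDisp; 5 were lower adjusted over the list alone (camera adjusted p 0.33).

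**Figure D4:**
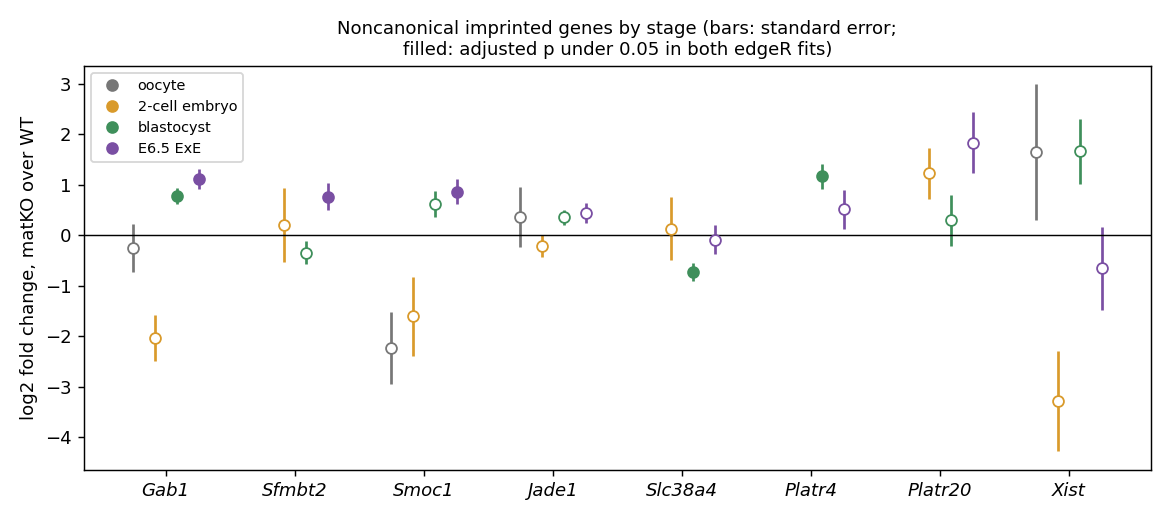
Log2 fold change (matKO over WT) of noncanonical imprinted genes at each stage, with both sexes in the model; error bars are standard errors and filled points passed an adjusted p of 0.05 in both edgeR fits. Gab1 is at -2.04 in 2-cell embryos, 0.77 in blastocysts and 1.11 in ExE.

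Libraries also stood apart by prefix. On the first principal component, 34% of the variance, the 8 matKO blastocysts of D707T lay at 63.8 to 93.2 and the 4 WT of D707T at 1.7 to 46.7, whereas D405T held 6 matKO at -40.5 to 5.8 and 10 WT at -79.6 to -23.9. The difference of the genotype effect between the prefixes was called for 196 genes (162 with estimateDisp). Within D405T 3 of 8 core noncanonical imprinted genes were higher and 1 lower, and within D707T 1 and 1 (3 and 1, and 0 and 0, with estimateDisp; 5 and 1, and 1 and 1, adjusted over the list alone). Gab1 was at 1.01 in D405T (adjusted p 1.6e-04) and 0.29 in D707T (adjusted p 0.65), with an adjusted p of 0.32 for the difference.

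Some trophectoderm genes, markers of the lineage that forms the placenta, were lower in matKO blastocysts. Gata2, a regulator of trophoblast genes, fell by 2.14 (adjusted p 1e-05, and 2.6e-04 with estimateDisp), and the keratin Krt18 by 1.08, from 1790 CPM ± 692 (SD, n = 14) to 732 CPM ± 527 (SD, n = 14) (adjusted p 4.4e-04, and 0.0018). Each was under the WT mean in 14 of 14 embryos and below every WT embryo in 8. Gata2 and Krt18 were at -1.97 and -0.72 within D405T (adjusted p 0.0066 and 0.0071) and at -6.28 and -1.62 within D707T (adjusted p 0.0038 and 0.017). Of 23 tested, 8 fell and 0 rose (6 and 0 with estimateDisp), and 9 were lower and 1 higher adjusted over the list alone (camera adjusted p 0.043; adjusted p = 0.27 with an estimated correlation). Within D405T 4 of 24 were lower and 0 higher, and within D707T 4 of 21 were lower and 1 higher (3 and 0, and 4 and 0, with estimateDisp; 7 and 0, and 7 and 3, adjusted over the list alone). Some genes of glycolysis were lower as well, 8 of 16 with 1 higher (4 and 0 with estimateDisp; 10 and 1 adjusted over the list alone), with a camera adjusted p of 4.4e-04 and an adjusted p = 0.12 with an estimated correlation. They include X-linked Pgk1, which fell by 2.73 (adjusted p 2.1e-06, and 3.6e-04; 14 of 14 embryos), and autosomal Tpi1, which fell by 1.14 (adjusted p 0.003, and 0.0076; 14 of 14). Within D405T 4 of the 16 were lower and 0 higher, and within D707T 1 and 1 (4 and 0, and 0 and 0, with estimateDisp; 11 and 0, and 2 and 1, adjusted over the list alone). Of 17 targets of p53, 5 rose and 0 fell (2 and 0 with estimateDisp; 5 and 0 adjusted over the list alone; camera adjusted p 4.4e-04; adjusted p = 0.12 with an estimated correlation). Tigar, a regulator of glycolysis, rose by 0.60 in 14 of 14 (adjusted p 0.0014, and 0.0034) and X-linked Eda2r by 2.07 in 13 of 14 (adjusted p 2.4e-04, and 0.041). Within D405T 7 p53 targets were higher and 0 lower, and within D707T 0 and 0 (2 and 0, and 0 and 0, with estimateDisp; 9 and 1, and 0 and 0, adjusted over the list alone). Immediate early and stress genes had 4 of 16 higher and 2 lower (2 and 0 with estimateDisp; 6 and 2 adjusted over the list alone; camera adjusted p 0.032; adjusted p = 0.17 with an estimated correlation), led by Atf4 at 0.54 in 14 of 14. Ribosome biogenesis had 1 of 22 higher, Polr1b, also with estimateDisp and adjusted over the list alone (camera adjusted p 0.032; adjusted p = 0.43 with an estimated correlation).

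Markers of the inner cell mass moved both ways. Nanog, a pluripotency factor, rose by 0.60 (adjusted p 0.0039, and 0.0088 with estimateDisp) in 12 of 14 embryos and Tfcp2l1 by 0.47 (adjusted p 0.003, and 0.0054) in 14 of 14, whereas Prdm14 fell by 2.23 (adjusted p 3.2e-05, and 0.0012) and Spp1 by 2.08 (adjusted p 0.0033, and 0.0067), each in 14 of 14. The list had 5 higher and 3 lower of 17 (4 and 2 with estimateDisp; 6 and 4 adjusted over the list alone; camera adjusted p 0.37), and 1 higher and 2 lower within D405T and 0 and 3 within D707T (5 and 4, and 4 and 3, adjusted over the list alone). Gata6, a primitive endoderm regulator, rose by 0.75 (adjusted p 4.9e-04, and 0.0019) in 12 of 14 and the basement membrane gene Lamb1 fell by 1.28 (adjusted p 0.0049, and 0.011) in 14 of 14; that list had 2 higher and 4 lower of 16 (1 and 1 with estimateDisp; 2 and 7 adjusted over the list alone; camera adjusted p 0.29), and 2 higher and 2 lower of 17 within D405T and 0 and 0 within D707T (2 and 9, and 0 and 0, adjusted over the list alone). The largest rises included the homeobox gene Rhox5, 4.12 ± 0.48 (SE), Prl3b1, 2.80, and Wbp5, 2.24, each in 13 of 14 embryos and each called by both fits. The largest falls included the X-linked genes Plac1, needed in placenta, -5.42, Fthl17a, -4.46, and Rnf128, -3.91, each in 14 of 14 and called by both fits. Below every WT embryo lay 13 of 14 for Plac1, 13 for Fthl17a and 0 for Rnf128. Rhox5 and Fthl17a belong to multicopy families and are uncertain. X-linked Magea1, also of a multicopy family and uncertain, had 2 counts in WT and 566 in matKO, a ratio of 275 with a counting interval of 76.3 to 2270. All of these came from females, at 3.94 CPM ± 3.82 (SD, n = 7) in matKO and 0.0165 CPM ± 0.0259 (SD, n = 6) in WT (adjusted p 1.2e-04, and 0.022 with estimateDisp). It was at 0 in all 8 WT and all 7 matKO males, and the difference between the sexes was not called (adjusted p 1).

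In all, edgeR called 1796 of 13445 genes in blastocysts, 750 higher and 1046 lower, and the fit with estimateDisp called 847, of which 828 were shared. By sex the counts were 280 in females and 677 in males (28 and 205 with estimateDisp). Rdx, a membrane linker, Nedd4, a ubiquitin ligase, and Hsd17b6, a steroid enzyme, fell in both sexes by both fits, with male values of -2.27, -2.61 and -3.54 and female values of -2.06, -2.14 and -3.37. Within prefixes edgeR called 1204 genes in D405T and 457 in D707T for both sexes together (754 and 140 with estimateDisp); the males alone gave 269 in D405T and 153 in D707T, and the females 86 and 3. The share of called genes that were higher was 41.8%.

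ExE of day 6.5 tests whether effects lasted past implantation. Gab1 rose in matKO ExE to 432 CPM ± 85.2 (SD, n = 8) from 201 CPM ± 61.9 (SD, n = 10), a log2 fold change of 1.11 ± 0.20 (SE; adjusted p 2.9e-04, and 4.7e-04 with estimateDisp), and all 8 matKO samples lay above all 10 WT samples. Smoc1, a secreted calcium-binding protein, rose by 0.86 (adjusted p 0.012, and 0.016) in 8 of 8, and Sfmbt2, a Polycomb gene needed in trophoblast, by 0.76 (adjusted p 0.038, and 0.049) in 7 of 8. Platr20 was called at 1.83 (adjusted p 0.022) in 5 of 8 but not with estimateDisp (adjusted p 0.14). Slc38a4, Jade1, Xist and Platr4 had values of -0.09, 0.44, -0.66 and 0.51 and were not called. So 4 of 8 noncanonical imprinted genes rose and 0 fell (3 and 0 with estimateDisp), also 4 and 0 adjusted over the list alone, with a camera adjusted p of 0.058. Every comparison in ExE is also one between identifier prefixes, since the prefixes D1042C and D707T each held 1 genotype. Of all tested ExE genes 31.2% were called, so a list with about this share of called members does not stand out by its count.

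Among canonical imprinted genes in ExE, H19 rose by 1.33 (adjusted p 0.0047, and 0.0069 with estimateDisp), in 6 of 8, and the growth-restraining genes Cdkn1c and Phlda2 by 1.40 (adjusted p 8.1e-04, and 0.0013) and 2.16 (adjusted p 0.0057, and 0.009), in 7 and 6 of 8. Of 15 maternally expressed genes 4 rose and 2 fell (4 and 1 with estimateDisp; 4 and 2 adjusted over the list alone; camera adjusted p 0.72). Dlk1 fell by 2.41 (adjusted p 2.4e-04, and 6.6e-04) and Peg3 by 0.90 (adjusted p 0.0097, and 0.013), in 8 and 7 of 8; 4 of 22 paternally expressed genes fell and 1 rose, also with estimateDisp and adjusted over the list alone (camera adjusted p 0.058).

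Some markers of the ectoplacental cone and of trophoblast giant cells, which lie beyond the ExE, were higher in matKO ExE. The giant cell hormone genes Prl3d1 and Prl3d2 were at 5.76 and 5.78 (adjusted p 0.0018 and 0.0019; 0.0067 and 0.0068 with estimateDisp), in 7 of 8 samples each, with matKO levels of 178 CPM ± 285 and 179 CPM ± 277 (SD, n = 8); these near-identical copies are uncertain. Hand1 rose by 2.55 (adjusted p 0.0011, and 0.0022) in 6 of 8. Of 15 tested, 9 rose and 0 fell (8 and 0 with estimateDisp), 10 were higher adjusted over the list alone, and the median was 2.28 (camera adjusted p 3.4e-04; adjusted p = 0.36 with an estimated correlation). Markers of maternal decidua and uterine stroma had 11 of 17 higher and 0 lower (9 and 0 with estimateDisp; 12 and 1 adjusted over the list alone), with a median of 3.00 (camera adjusted p 0.0011; adjusted p = 0.71 with an estimated correlation). They include the collagen Col3a1 at 4.36 (adjusted p 3.7e-04, and 0.01) in 4 of 8 and Wnt4 at 3.20 (adjusted p 1.7e-04, and 0.0057) in 7 of 8. Their mean level was 0.89 log2 CPM ± 0.78 (SD, n = 10) in WT and 2.58 log2 CPM ± 1.39 (SD, n = 8) in matKO, with 4 of 8 matKO samples above every WT sample. Y-linked genes had 1 of 4 lower, Ddx3y, at 40.6 CPM ± 8.84 (SD, n = 3) in matKO and 123 CPM ± 39.5 (SD, n = 4) in WT males, a log2 fold change of -1.67 over both sexes (adjusted p 0.028, and 0.092 with estimateDisp). Adjusted over the list alone 3 were lower, with a median of -1.50 (camera adjusted p 0.33), while Eif2s3y was at 0.24 (adjusted p 0.73). Parietal endoderm had 4 of 13 higher (1 with estimateDisp; 5 adjusted over the list alone; camera adjusted p 0.0043; adjusted p = 0.71 with an estimated correlation). Blood and endothelial markers had 5 of 9 higher and 1 lower (4 and 1 with estimateDisp; 6 and 1 adjusted over the list alone; camera adjusted p 0.096). Among them were the globin gene Hba-a1, uncertain because it has a near-identical copy, at 4.43 and Pecam1 at 2.68, in 5 and 7 of 8.

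Some genes of glycolysis were higher in matKO ExE. Of 16 genes 10 rose and 1 fell (9 and 1 with estimateDisp; 12 and 1 adjusted over the list alone; camera adjusted p 7.1e-04; adjusted p = 0.54 with an estimated correlation). Pfkl rose by 1.92 in 8 of 8 (adjusted p 2.5e-06, and 4.8e-06), and Gapdh by 2.40, from 754 CPM ± 498 (SD, n = 10) to 3960 CPM ± 2420 (SD, n = 8), in 7 of 8 (adjusted p 2.7e-04, and 5.3e-04). Of 16 targets of p53, 7 rose and 0 fell (6 and 0 with estimateDisp; 7 and 1 adjusted over the list alone; camera adjusted p 0.0087; adjusted p = 0.36 with an estimated correlation). Immediate early and stress genes had 8 of 19 higher and 5 lower (6 and 4 with estimateDisp; 8 and 5 adjusted over the list alone; camera adjusted p 0.29). Cholesterol synthesis had 4 of 18 higher and 4 lower (3 and 4 with estimateDisp; 4 and 4 adjusted over the list alone; camera adjusted p 0.86). The death effector and p53 target Bax rose by 2.42 ± 0.24 (SE; adjusted p 4e-07, and 1e-06) and the p53 target Phlda3 by 2.55 (adjusted p 4.6e-05, and 1.5e-04), above every WT sample in 8 of 8. Klf5, a regulator of trophoblast stem cells, rose by 3.09 (adjusted p 2.9e-08, and 2.4e-07) and the kinase gene Stk11 by 2.62 (adjusted p 1.1e-08, and 5.9e-08), above every WT sample in 8 of 8.

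**Figure D5:**
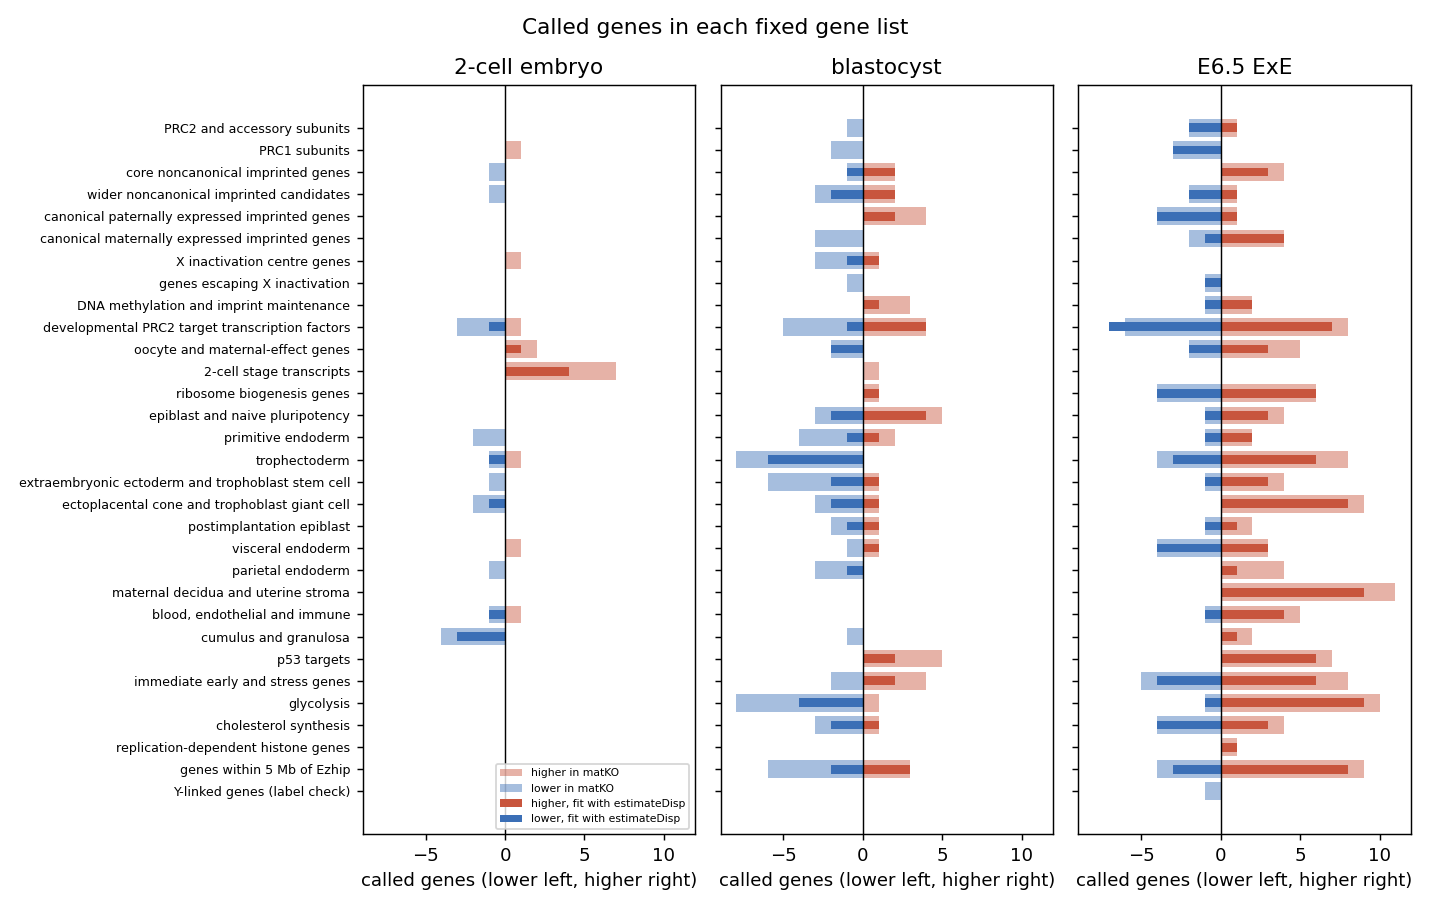
Number of called genes in each gene list, lower in matKO to the left and higher to the right, in 2-cell embryos, blastocysts and ExE. Pale bars are the main edgeR fit and dark bars the fit with estimateDisp; in ExE 11 genes of the decidua list were higher and 0 lower.

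The largest falls in ExE included single genes of several kinds. Mesp1 and T, markers of the primitive streak and early mesoderm, fell by 7.26 (adjusted p 0.006, and 0.018 with estimateDisp) and 3.68 (adjusted p 7.1e-04, and 0.0047), and the blood regulator Tal1 by 5.43 (adjusted p 2.7e-04, and 0.0066), each in 8 of 8. The WT levels of Mesp1, 29.9 CPM ± 71.4 (SD, n = 10), varied widely. Cntfr and Flt3, receptors of a neurotrophic factor and of a blood growth factor, fell by 5.17 (adjusted p 3.2e-06, and 5.8e-05) and 3.91 (adjusted p 3.5e-04, and 0.0049), each in 8 of 8. Below every WT sample lay 0 of 8 matKO samples for Mesp1 and for Tal1, 7 for T, 8 for Cntfr and 6 for Flt3. Among the largest rises were the cytokine gene Il24, 7.58 ± 1.19 (SE), in 5 of 8, and Sbsn, 6.29 ± 0.87 (SE), in 7 of 8. Mrps34 had 3 counts in WT and 1326 in matKO, a ratio of 533 with a counting interval of 182 to 2580. That interval covers counting error only, and whether the difference follows the genotype or the prefix cannot be told.

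In all, edgeR called 4417 of 14156 genes in ExE, 2462 higher and 1955 lower, and the fit with estimateDisp 3520, of which 3514 were shared. Without the 4 matKO samples high in decidua markers the count was 2346, and with the GC trend of each library removed it was 3202. By sex 2165 genes were called in females and 1218 in males (1372 and 748 with estimateDisp). The edgeR interaction called 0 genes, with 700 at an unadjusted p under 0.05 (513 with estimateDisp), and DESeq2 also called 0. Tmem259, Akap8l and Vars rose in both sexes by both fits, with female values of 4.75, 3.27 and 2.81 and male values of 4.98, 3.8 and 3.21. X-linked genes had 101 lower and 57 higher of 546 (79 and 41 with estimateDisp; 96 and 56 adjusted over the list alone; camera adjusted p 0.079). Thus 18.5% of X-linked genes fell against 13.6% of autosomal genes, with 4.95% against 5.08% in females and 5.68% against 2.51% in males. The median log2 fold change of chromosome X was -0.323, and those of autosomes ran from -0.305 to 0.12. X-linked output relative to autosomes differed by -0.15 in females (exact permutation p 0.126). In males it differed by -0.45 (exact permutation p 0.0571, smallest possible 0.0286, with 4 WT and 3 matKO). The difference between the sexes was 0.31 (permutation p 0.209). Every ExE library labelled male held Xist, at 10.4 CPM or more, so female RNA in these libraries stays open.

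Genes called at 1 stage overlapped little with those of another. Among 11481 genes tested at both stages, 29 were lower in 2-cell embryos and blastocysts where 17.2 are given by chance (Fisher's exact p 0.005, adjusted 0.03), and 9 were higher where chance gives 5.06 (Fisher's exact p 0.1, adjusted 0.2). The lower overlap was not past the threshold with the calls of DESeq2 (21 genes) or estimateDisp (4 genes). Between 2-cell embryos and ExE, 44 genes were lower where chance gives 32.3 (Fisher's exact p 0.028, adjusted 0.084) and 12 were higher where chance gives 12.8 (Fisher's exact p 1). Between blastocysts and ExE, 105 were higher and 134 lower where chance gives 106 and 131 (Fisher's exact p 1 and 0.77). Across genes, which are not independent replicates, fold changes of these stage pairs had Pearson r of 0, -0.03 and -0.01 and Spearman rho of -0.02, -0.03 and 0.01.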

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

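The tests of the identifier prefix, of wrong sex labels, of female RNA and of expression-matched autosomal genes were chosen after the result was seen.

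Xist responded to genotype differently in the sexes of blastocysts, with a female minus male difference of -5.78 on the log2 scale (edgeR adjusted p 1.4e-04). Compared without regard to the prefix, X-linked output was lower in matKO males (-0.85) and in matKO females (-0.61, exact permutation p 0.00816). D707T held 1 of the WT females but 4 of the matKO females. Within D405T the male and female differences were -0.5 and -0.24. With the prefix as a term, female Xist differed by -0.18 (adjusted p 0.92). The female minus male difference in output, without regard to the prefix, had a permutation p of 0.543. As a set fitted with the prefix, X-linked genes differed between the sexes (camera p 2.1e-06, and 0.019 with an estimated correlation). A difference between the prefixes is argued against, since within each prefix every matKO male had more Xist than every WT male, with smallest gaps of 2.3 log2 units in D405T and 2.52 in D707T, and X-linked output was lower in both; dropout of weakly expressed genes is argued against by a male difference of -0.82 from expression-matched autosomal genes, and wrong sex labels by Y-linked levels of at least 36.2 CPM in matKO males and at most 0.327 CPM in female blastocysts. Female RNA mixed into matKO male libraries is argued against as the cause of their lower X-linked output. That output lay below that of matKO females by a mean of -0.40 over the prefixes (exact permutation p 0.0157). A mixture would lie between WT males and matKO females. For Xist, female RNA stays open. Over both prefixes Y-linked genes of matKO males differed by -25.1 CPM from WT males (exact permutation p 0.367). Female RNA that brought all Xist of matKO males would give -29.2 CPM. Within D405T Y-linked genes stood at 141 to 216 CPM in matKO males and 129 to 235 CPM in WT males. Within D707T they stood at 36.2 to 99.3 CPM in matKO males and 82.3 to 145 CPM in WT males. An effect of maternal genotype stays open, as do donor, litter and culture. Library order stays open within D707T, where WT blastocysts had identifier numbers 1 to 4 and matKO blastocysts 5 to 12. Within D405T, where the numbers of the genotypes were interleaved, the male differences in Xist and in output went the same way. In males, loss of the maternal product and of the embryo's own Ezhip copy cannot be told apart. A male has only the maternal X, so Xist made by the male embryos would come from that X. Which X chromosome expressed Xist in females was not tested.

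Other splits of the 28 blastocysts bear on whether chance can be excluded for these counts. For the genotype effect 1 of 100 splits, the real one, gave as many genes (1796, highest other 42), and with estimateDisp 1 of 50 (847, highest other 5). This argues against chance among single libraries but not against differences between donors or litters, which are not given. The same holds in females (280; highest other 45; 1 of 100) and males (677; highest other 36; 1 of 100). For the interaction 17 of 100 splits called as many genes as the real one (1; highest other 333), so chance could not be excluded for that count, and a split with 333 genes points to a structure of the samples.

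Single libraries stood far from the rest of their group in 18 of 111 groups of values. Chance flags about 1 in 20 groups if values are normally distributed. Levels near the limit of detection are not, so the excess cannot be read as a sign of odd libraries. Among oocytes, Gab1 was at 18.1 CPM in matKO oocyte 3. In 2-cell embryos Ezhip was at 18.9 CPM in matKO female 6 and 8.69 CPM in matKO male 4. Xist at this stage was at 13.9 CPM in matKO female 1, 81.4 CPM in WT female 1 and 3.59 CPM in WT male 5. Sfmbt2 was at 7.3 CPM in matKO female 6 and 6.27 CPM in WT female 5, and Smoc1 was at 5.72 CPM in matKO male 3. In blastocysts Ezhip was at 2.04 CPM in matKO female 7, 3.85 CPM in WT female 5 and 45.8 CPM in WT male 4. Xist was at 286 CPM in matKO male blastocyst 4, and Platr4 was at 10.9 CPM in WT male blastocyst 4. X-linked minus autosomal output was -0.669 log2 CPM in WT female blastocyst 5, the only D707T library of its group. In ExE, Xist was at 2500 CPM in WT female 4, Platr4 at 16.6 CPM in WT female 6 and Ezhip at 0 CPM in WT male 2.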

How the results depend on the processing

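The fits with estimateDisp for single sexes, named genes and overlaps, the GC, identifier-number and expression-matched fits, and those without libraries high in granulosa or decidua markers were tests chosen after seeing the data. Except where an alternative tests fewer genes, fewer samples or a larger fold by its construction, the cause was not tested. DESeq2 size factors moved no count of calls by over 1.5 times, and shifted the median of all genes by at most 0.021. DESeq2 called 36 genes in oocytes, 693 in 2-cell embryos, 27 in female 2-cell embryos and 4 for the blastocyst interaction; voom called 49 in 2-cell embryos. With estimateDisp the counts were 106 in 2-cell embryos (3 in females, 127 in males), 847 in blastocysts (28 and 205), and 1372 in female and 748 in male ExE. With no filter they were 1090 in 2-cell embryos (164 in females, 1475 in males, 201 for the interaction) and 783 in male ExE. With the identifier number they were 1039 in 2-cell embryos (22 in females, 2147 in males, 129 for the interaction). A fold of at least 2 left 1012 genes in blastocysts and 2807 in ExE. Leaving out WT libraries high in granulosa markers gave 1356 genes in 2-cell embryos, and leaving out matKO libraries high in decidua markers gave 2346 in ExE. Without the prefix term male blastocysts had 431. D405T alone gave 86 in females and 269 in males, and D707T alone 457 in both sexes, 3 in females, 153 in males and 0 for the interaction.

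Replicate numbers did not pair the samples: correlations of same-numbered samples were not all over 0.1. With the number as a block, over the samples that share one, the counts were 1 in oocytes, 85 in 2-cell embryos, 1327 in blastocysts and 3411 in ExE, and not every sample correlated best with its own number. Leaving out each library in turn gave 1 to 4 genes in oocytes (1 without matKO oocyte 1), 1291 to 1895 in blastocysts and 3800 to 4665 in ExE. In 2-cell embryos it gave 245 to 736, with 256 without WT female 1, 686, 736 and 288 without matKO females 1, 4 and 6, and 260, 296, 245, 284 and 261 without matKO males 1, 2, 3, 5 and 6. The Ezhip change ranged from -12.79 to -11.84 in oocytes, from -6.12 to -5.26 in 2-cell embryos and from -4.29 to -3.11 in blastocysts.

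X-linked output in male 2-cell embryos, -0.01 and not past the test, became 0.11 as a median and 0.03 over genes with at least 10 CPM, and ran from -0.06 to 0.03 with a library left out. It was -1.06 in male D707T blastocysts (exact permutation p 0.0571), and with a library left out ran from -0.95 to -0.74 in male and -0.69 to -0.52 in female blastocysts. Lower genes shared by 2-cell embryos and blastocysts numbered 21 with DESeq2, 2 at a threshold of 0.01 and 4 with estimateDisp. Those of 2-cell embryos and ExE numbered 49, 4 and 7, and 19 higher genes were shared with DESeq2, fewer than the 30.6 of chance. Blastocysts and ExE shared 64 lower genes with estimateDisp. Among genes that were not called, Sfmbt2 in 2-cell embryos became -0.10 with estimateDisp, -0.08 with DESeq2 and ran from -0.05 to 0.94 with a library left out, and Slc38a4 ran from -0.13 to 1.01. Platr20 in blastocysts became -0.22 with estimateDisp, -0.24 with DESeq2 and ran from -0.15, without matKO male 3, to 0.48. Gab1 in oocytes ran from -0.69 to 0.17, the latter without WT oocyte 2, and in ExE Slc38a4 ran from -0.23 to 0.05 and Xist from -1.77 to 0.12, both highest without WT female 4. Of called named genes, estimateDisp lost 0 of 2 in oocytes, 17 of 35 in 2-cell embryos, 29 of 86 in blastocysts and 8 of 106 in ExE, and DESeq2 lost 0, 8, 14 and 4. The estimated correlation ended all list calls, 2, 3, 6 and 5 by stage, fry ended 2, 2, 1 and 1 of them and added 0, 0, 2 and 3, and DESeq2 size factors ended 0. The lowest depth was 1.05 M counts, in a WT 2-cell embryo.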

Other observations

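The tests with the identifier number, with GC content, of the ExE prefix, and without libraries high in granulosa or decidua markers were chosen after seeing the data.

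Genes around the X inactivation centre, where Xist lies, moved apart in matKO blastocysts. Ftx, a noncoding activator of Xist, rose by 1.16 (edgeR adjusted p 0.018, and 0.04 with estimateDisp) in 9 of 14 embryos, while Chic1 fell by 2.33 in 14 of 14 (adjusted p 9.1e-06, and 0.0028), and Tsx and Rlim fell by 1.64 and 0.77 in 12 and 13 of 14 (adjusted p 0.021 and 0.042; 0.17 and 0.097 with estimateDisp). This made 1 of 5 higher and 3 lower (1 and 1 with estimateDisp), or 2 and 3 adjusted over the list alone (camera adjusted p 0.37). Of the ExE and trophoblast stem cell markers in blastocysts, 6 of 19 fell and 1 rose (2 and 1 with estimateDisp; 4 higher and 6 lower adjusted over the list alone; camera adjusted p 0.83), among them Eomes, -0.88, and Ets2, -2.91, in 13 and 14 of 14 embryos, both called by both fits. Enzymes of cholesterol synthesis had 3 of 18 lower and 1 higher (2 and 1 with estimateDisp, 4 and 1 adjusted over the list alone, camera adjusted p 0.94). X-linked Nsdhl led them at -1.96 in 14 of 14 (adjusted p 8.9e-06, and 2.6e-04). It was at -1.47 within D405T and -4.84 within D707T, and the effect differed between the prefixes (adjusted p 0.0075, and 0.0045). The list had 3 higher and 2 lower within D405T and 0 higher and 3 lower within D707T.

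In ExE the keratin genes Krt8 and Krt19 rose by 1.83 and 2.62 (edgeR adjusted p 8.5e-04 and 8.1e-04; 0.0015 and 0.0017 with estimateDisp), each in 7 of 8 samples, with 8 of 24 trophectoderm genes higher and 4 lower (6 and 3 with estimateDisp; 8 and 4 adjusted over the list alone; camera adjusted p 0.29). ExE and trophoblast stem cell markers had 4 of 23 higher and 1 lower (3 and 1 with estimateDisp and also adjusted over the list alone; camera adjusted p 0.61). Visceral endoderm markers had 3 of 22 higher, led by the apolipoprotein gene Apoa4 at 3.00 in 8 of 8, and 4 lower, also with estimateDisp and adjusted over the list alone (camera adjusted p 0.86). Of all tested ExE genes 31.2% were called. Genes within 5 Mb of Ezhip had 0 of 42 called in oocytes, 0 of 51 in 2-cell embryos, 3 higher and 6 lower of 45 in blastocysts, and 9 higher and 4 lower of 48 in ExE (camera adjusted p 0.96, 0.6, 0.94 and 0.66; adjusted over the list alone 0, 0, 4 higher and 6 lower, and 9 higher and 4 lower; with estimateDisp 0, 0, 3 higher and 2 lower, and 8 higher and 3 lower).

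Many genes were called in matKO ExE, and no technical explanation for this pattern as a whole was settled. Library composition differed between the genotypes. The 50 most abundant genes held 15.4% to 23% of the counts in WT libraries and 23.1% to 32.7% in matKO libraries. Whether this difference is technical was not tested. A trend with GC content is argued against as the whole cause: fold changes followed GC content across genes (Spearman rho 0.43, over genes, which are not independent replicates), and with the trend removed (rho 0.02) 3202 genes were called. Without the 4 matKO samples high in decidua markers, 2362 of the 2462 genes called higher had a median of 1.25, against 1.35 with them. These genes were chosen from the same samples. The other matKO samples were not free of these markers either, with a lowest level of 1.17 log2 CPM against a WT mean of 0.89. The test thus cannot decide whether decidua is the whole cause. Maternal RNA as a part of it stays open, with 3 of 4 Y-linked genes lower adjusted over the list alone (median -1.50). The prefix and the genotype cannot be told apart, since 0 prefixes held both. A genotype effect in ExE may thus be mixed with a batch effect of unknown size.

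Genes lower in matKO 2-cell embryos included markers of granulosa cells, so RNA of these cells in WT embryos is a candidate source. The 8 of 11 WT embryos high in these markers and in those of uterine stroma were left out. Over 240 of the 255 genes called lower the median was then -1.94, against -1.66 with them. These genes were chosen from the same data, so this test cannot decide whether granulosa RNA is the whole cause. The fall of Cyp11a1, Hsd3b1, Inha and Star themselves stays open. With the identifier number as a covariate 1039 genes were called, but this test cannot decide: the numbers ran from 25 to 36 in WT and from 37 to 48 in matKO and were centred within genotype, so the bound set for this test was wrong and order and genotype cannot be told apart. An effect of maternal genotype stays open as well, with donors untested.

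In order of identifier number, from 37 to 48, matKO 2-cell libraries had Ezhip counts of 4, 86, 12, 25, 31, 0, 2, 0, 1, 0, 0 and 31. Their scores on the first principal component, 27.4% of the variance, were -52.3, -26.7, -28.9, -14.5, -47.3, 49.9, 39.7, 63.4, 52.5, 69.8, 67.1 and 72.1 in the same order. Xist ran from 35.5 to 229 CPM in WT and from 10.4 to 426 CPM in matKO ExE libraries labelled male. WT female ExE libraries held 77.8 to 2500 CPM, and WT male blastocysts at most 4.1 CPM. Female RNA in male ExE libraries of both genotypes stays open and was not tested.

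The hypothesis that X-linked genes nearer to Xist fell more in matKO male blastocysts was not borne out. Across 466 X-linked genes, which are not independent replicates, Spearman's rho between distance from Xist and the male fold change was 0.16 (circular-shift permutation p 0.31).

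Other splits of the libraries bear on chance in the remaining comparisons. In oocytes 2 of 35 splits called as many genes as the real one (3; highest other 3), so chance could not be excluded. In 2-cell embryos the real split stood alone among 100 for the genotype effect (454, highest other 274). It also did for females (10, highest other 8) and for males (807, highest other 721). With estimateDisp it was 1 of 50 (106, highest other 1). This argues against chance among single libraries but not against the identifier order, which separates the genotypes. For the interaction the real count was 0, which all 100 splits reach by construction, so the splits say nothing about chance; 1 of them called 1663 genes, which points to a structure of the samples. In ExE the real split stood alone among 100 for the genotype effect (4417, highest other 125). It also did for females (2165, highest other 537) and for males (1218, highest other 211). With estimateDisp it was 1 of 50 (3520, highest other 6). These splits argue against chance among single libraries, but not against the prefix, nor against donor or litter, which are not given. The ExE interaction also had a real count of 0, reached by all 100 splits by construction (highest other 65), which says nothing about chance.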
